A study of Mus musculus with 6 samples.

How the data were processed

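RNA was measured in 6 libraries of sorted mouse kidney cells, 3 of tdT+GFP+ and 3 of tdT-GFP+ cells. Per the labels' protocols, the tissue was dissociated on ice with a cold-active protease and Liberase, cells were sorted by fluorescence with debris and doublets gated out, and poly(A) RNA was made into strand-specific libraries. Whether the counting used the strand is not given in the sources used here, so antisense and overlapping genes may share reads. The labels name 3 biological replicates per group, from kidneys 1, 2 and 3.

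The deposited table holds estimated counts per gene (RSEM expected counts, per the file headers), and its values were already whole numbers, so that rounding changed none. The submitters' processing notes list bcl2fastq 2.20, STAR 2.6.1, RSEM 1.2.28, DESeq2 1.26.0 and R 3.6.3. They name the builds mm10 and GRCh38 without a role, and the annotation release is not given in the sources used here. The table has 31815 mouse gene rows and 92 rows of ERCC spike-in controls that are 0 in all libraries and were left out. With their version numbers left off, 31748 of the gene identifiers were found in the GENCODE M21 annotation of GRCm38. The coordinates were taken from it by the same match, and 41 symbols stand on more than 1 row. Library totals are the sums over genes. A count of 3 corresponds to 0.0908 to 0.117 CPM in these libraries, and the spread between libraries, not the depth, sets the precision of the abundant genes named.

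Genes were filtered with filterByExpr by group, scaled by TMM and tested with edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The model held the group alone. Log2 fold changes are unshrunken coefficients, the SE is the coefficient divided by the square root of its F value, and CPM are on TMM-scaled library sizes. A list's per-library mean is of log2 CPM with a prior count of 2. The 30 gene lists (568 genes, 535 tested, no gene in more than 1 list) were fixed before the data were examined, as were the designs and alternatives other than the added one named in the closing section. The 29 lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. The preset called 5 lists higher and 7 lower, and the estimated correlation called 0 (smallest adjusted p = 0.287). The fry test, which asks whether a list's genes move on balance in one direction, also called 0 (smallest adjusted p = 0.170). The estimated correlation ran from -0.050 for the senescence list to 0.862 for the macrophage list, with 0.503 for endothelial and 0.677 for interferon genes. Where it lies far above 0.01, the preset p-value takes members that vary together as nearly independent. Enrichment of the lists among DESeq2 calls used Fisher's exact test over the 14559 genes with an adjusted p in DESeq2. This test takes genes as independent, while members of a list can vary together across the 6 libraries. Its p-values do not measure the spread between kidneys.

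Genes were named by a rule: Axin2, Acta2, Sox9 and Cdh6 always; per direction the 10 genes with the largest fold change among those past the threshold with a mean of at least 1 CPM and the same direction in all 3 kidneys, leaving out predicted models; and up to 4 members per list with the smallest adjusted p. As no gene passed, the 10 per direction are those with the smallest unadjusted p under the same filters. The text names only part of the list members that the rule allows, and a result among them is not reported here.

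The same-numbered libraries come from the same kidney per the labels, so the numbers pair them. The deviations from the group means correlated across genes by 0.04, -0.58 and -0.30 for kidneys 1, 2 and 3. Replicate 2 of tdT+GFP+ cells with replicate 3 of tdT-GFP+ cells and replicate 3 of tdT+GFP+ cells with replicate 2 of tdT-GFP+ cells correlated by 0.448 and 0.444. Deviations cancel out within each group, so these correlations depend on each other and cannot decide whether a number is wrong. Whether kidney numbers 2 and 3 are right in both sorts stays open. The values per kidney and with the kidney as a block rest on the numbers in the labels. Across genes, log2 CPM correlated by 0.970 to 0.988 within and 0.960 to 0.986 between groups. No 2 libraries agreed within counting noise.

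Alternatives were DESeq2 size factors and upper-quartile factors, no filter and a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom 3.58.1 with and without quality weights, the kidney as a block in edgeR and DESeq2, leaving out mitochondrial, ribosomal protein and haemoglobin genes, the estimated correlation, and leaving out each library or kidney in turn. The procedure was tested on simulated data drawn from these libraries' means and sizes, with 200 changed genes among 15462 in each of 5 simulations. After the filter 15250 genes were tested on average, and recovery was counted over the changed genes that passed the filter. For tdT+GFP+ against tdT-GFP+ cells, it recovered 16.1% of 1.5-fold, 47.3% of 2-fold, 82.8% of 4-fold and 94.0% of 8-fold changes. Of 653 calls 8.58% were false. Each simulated gene was drawn independently, without the variation that many genes share across the real libraries, so recovery in the real data may differ.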

Results

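Messenger RNA was sequenced from cells sorted out of the cortex and outer medulla of mouse kidneys 6 days after bilateral ischemia reperfusion injury, a surgery that interrupts and then restores the blood supply of the kidneys. The male mice carried a tamoxifen-inducible Cre recombinase in the Axin2 gene, a Cre-dependent red fluorescent reporter (tdTomato, tdT) and a green fluorescent protein (GFP) driven by Acta2, the gene of smooth muscle actin. Axin2 is a feedback target of canonical Wnt signalling, and Acta2 is the usual marker of myofibroblasts. Tamoxifen on days 2 and 4 gave a lasting red label to cells that used Axin2 around those times. The 6 libraries were 3 of tdT+GFP+ cells and 3 of tdT-GFP+ cells, and kidneys 1, 2 and 3 each gave a library of both kinds. Total counts were 33029933, 31458682 and 26919514 in tdT+GFP+ libraries 1, 2 and 3 and 31337198, 26096727 and 25697348 in tdT-GFP+ libraries 1, 2 and 3. The design asks how myofibroblasts with a history of Wnt activity differ from other GFP+ cells of the same injured kidneys. Positive log2 fold changes below mean higher in tdT+GFP+ cells.

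The levels of Axin2 mRNA itself overlapped between the populations at the time of the sort, with wide scatter between libraries. Axin2 (ENSMUSG00000000142.15, GRCm38 chromosome 11, 108920349 to 108950783, plus strand, protein coding) had a normalised count of 48.9 ± 17.6 CPM in tdT+GFP+ cells and 44.9 ± 18.5 CPM in tdT-GFP+ cells (SD, n = 3 each). The log2 fold change was 0.12 (SE 0.38, 95% interval -0.79 to 1.03, adjusted p = 0.907, edgeR quasi-likelihood test), and Axin2 was higher in tdT+GFP+ cells in 2 of 3 kidneys. The sign turned without replicate 3 of tdT+GFP+ cells (-0.12), without replicate 3 of tdT-GFP+ cells (-0.13) and without both (-0.38), and the value without both libraries of replicate 2 was 0.72. Acta2 (ENSMUSG00000035783.9, chromosome 19, 34241090 to 34255590, minus strand, protein coding) was abundant in every library. It stood at 1580 ± 166 CPM in tdT+GFP+ cells and 1158 ± 372 CPM in tdT-GFP+ cells, a log2 fold change of 0.45 (SE 0.23, adjusted p = 0.499) that was not past the threshold, and 0.76 (adjusted p = 0.134) without replicate 1 of tdT-GFP+ cells. Sox9 (ENSMUSG00000000567.5, chromosome 11, 112782224 to 112787760, plus strand), a transcription factor of repairing kidney epithelium, had 13.4 ± 1.73 CPM against 25.1 ± 11.1 CPM. Its log2 fold change of -0.91 (SE 0.30, adjusted p = 0.438) was not past the threshold, with lower values in tdT+GFP+ cells in all 3 kidneys, and it was -0.48 without replicate 3 of tdT-GFP+ cells. Cdh6 (ENSMUSG00000039385.5, chromosome 15, 13028701 to 13173675, minus strand), a cadherin of proximal tubule progenitors, had a log2 fold change of -0.68 (SE 0.40, adjusted p = 0.533), and -0.12 without replicate 3 of tdT-GFP+ cells.

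**Figure D1:**
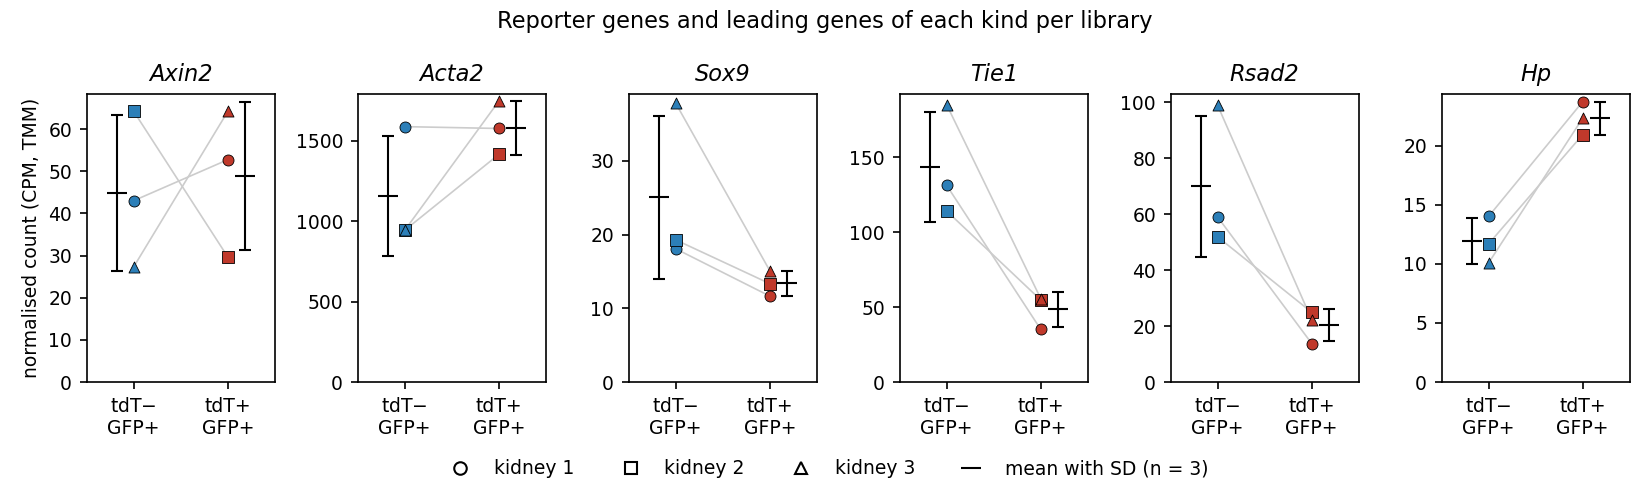
Normalised counts (CPM after TMM scaling) of Axin2, Acta2, Sox9, Tie1, Rsad2 and Hp in each library of tdT-GFP+ cells (blue) and tdT+GFP+ cells (red). Symbols mark kidneys 1 to 3, grey lines join libraries of 1 kidney, and bars give the mean and SD (n = 3); Axin2 overlaps between the groups, while Tie1 and Rsad2 are lower and Hp is higher in all 3 tdT+GFP+ libraries.

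No single gene passed the threshold in the edgeR test, and the genes with the smallest p-values had lower values in tdT+GFP+ cells more often than higher ones. Of 15462 genes tested, 0 were higher and 0 were lower at an adjusted p under 0.05, and the smallest adjusted p was 0.388. At an unadjusted p under 0.05 there were 573 genes with positive and 1077 with negative log2 fold changes, 1650 together, where 773 would be expected by chance. The 9 other splits of the libraries into 3 against 3 gave 27 to 2510 such genes, and 2 of them gave more than the real one. Of the 1650, 56 were more than 2-fold higher and 414 more than 2-fold lower. The values of 2448 genes (15.8%) did not overlap between the groups, where chance gives 10%. The DESeq2 Wald test on the same libraries called 17 genes higher and 264 lower, and 41 higher and 237 lower with the kidney as a block. The limma-voom test, with or without quality weights, called 0 genes.

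The 10 genes with negative fold changes and the smallest p-values were picked to be lower in tdT+GFP+ cells in each of the 3 kidneys. They included Zfp366, a zinc finger protein, at 9.28 ± 0.709 against 25.0 ± 6.17 CPM (log2 fold change -1.43, SE 0.18). Ushbp1 had 11.4 ± 1.12 against 32.6 ± 9.06 CPM (-1.52, SE 0.21), and the scavenger receptor gene Scarf1 had 22.2 ± 1.46 against 34.5 ± 1.76 CPM (-0.64, SE 0.09). Log2 fold changes were -0.86 for the heat shock protein gene Hspa12b, -1.06 for the GTPase gene Gimap5, -1.50 for the actin-binding protein gene Cap2, -1.57 for Fam167b, -1.41 for Ccm2l, -0.48 for Rcsd1 and -1.30 for Usp18, which encodes a protease that removes the interferon-induced modifier ISG15. The adjusted p of each of these 10 was 0.388, so none was past the threshold in edgeR, while DESeq2 called all 10, and 9 with the kidney as a block. The 10 genes with positive fold changes were led by Hp, which encodes the haemoglobin-binding protein haptoglobin, at 22.3 ± 1.39 against 11.9 ± 1.98 CPM (log2 fold change 0.90, SE 0.14, adjusted p = 0.388). The mesothelial gene Msln had the widest fold change of these, 1.82 (SE 0.42), from low levels of 1.59 ± 0.606 against 0.448 ± 0.129 CPM. The transcription factor gene Zbtb16 had 13.4 ± 5.48 against 5.03 ± 0.630 CPM (1.42, SE 0.34). Values were 0.56 for the amino acid transporter gene Slc38a1, 0.33 for the mitochondrial peroxiredoxin gene Prdx3, 0.51 for the serine synthesis gene Phgdh, 0.47 for Zfp970, 0.40 for the replication origin gene Orc2, 0.44 for Tmem97 and 0.38 for the small GTPase gene Rras2. The rule picked these 10 to be higher in tdT+GFP+ cells in each kidney. None was past the edgeR threshold (adjusted p from 0.388 to 0.399), and DESeq2 called 7 of them, or 2 with the kidney as a block. Both sets of 10 were picked by p-value in the same libraries, so their DESeq2 counts are no separate support.

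Canonical Wnt targets as a group did not pass the test, and their members went both ways. Of 16 tested Wnt target and feedback genes, 7 had positive and 9 negative log2 fold changes, the median was -0.05, and 0 passed when adjusted over the list alone or over all genes (camera adjusted p = 0.818). The negative feedback ligase genes Znrf3 and Rnf43 had log2 fold changes of 0.26 (SE 0.09) and -1.15 (SE 0.43), the latter at 0.803 ± 0.360 against 1.76 ± 0.613 CPM. The cyclin gene Ccnd1 had -0.48 (SE 0.30) and the transcription factor gene Tcf7 had 0.26 (SE 0.16), which fell to -0.18 and 0.10 without replicate 3 of tdT-GFP+ cells. Ccnd1 ranged from -0.95 without both libraries of replicate 2 to -0.03 without both of replicate 3. Without both libraries of replicate 2 the list was called higher (median 0.29, adjusted p = 0.0282), and without both of replicate 3 it was called lower (median -0.38, adjusted p = 0.0200). Of 13 tested Wnt ligands, 8 had positive values, with a median of 0.18, a mean of -0.05 and a test direction of up (adjusted p = 0.438, and 0.0492 without both libraries of replicate 1). Wnt16 had a log2 fold change of -2.67 (SE 0.77) at 0.428 ± 0.188 against 2.75 ± 2.17 CPM, and Wnt9a had 0.68 (SE 0.36), from 0.41 without replicate 2 to 1.22 without replicate 1 of tdT-GFP+ cells. Of 25 Wnt receptors and secreted modulators, 13 had positive values. Their median was 0.02, their mean -0.13 and the test direction down (adjusted p = 0.817), and the library means did not overlap between the groups. Values were -1.06 for the receptor gene Fzd6, -0.59 for Fzd4 and 0.61 for the secreted antagonist gene Frzb, the latter at 882 ± 80.3 against 576 ± 193 CPM. Without replicate 3 of tdT-GFP+ cells Fzd4 had -0.36 and Frzb 0.37. None of these lists had a member past the threshold over the list alone in edgeR, but with the kidney as a block 1 Wnt receptor gene passed. DESeq2 called Fzd6 lower (adjusted p = 0.0260, and 0.00072 with the kidney as a block) and Wnt16 lower (0.0333, and 0.181 with the block).

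**Figure D2:**
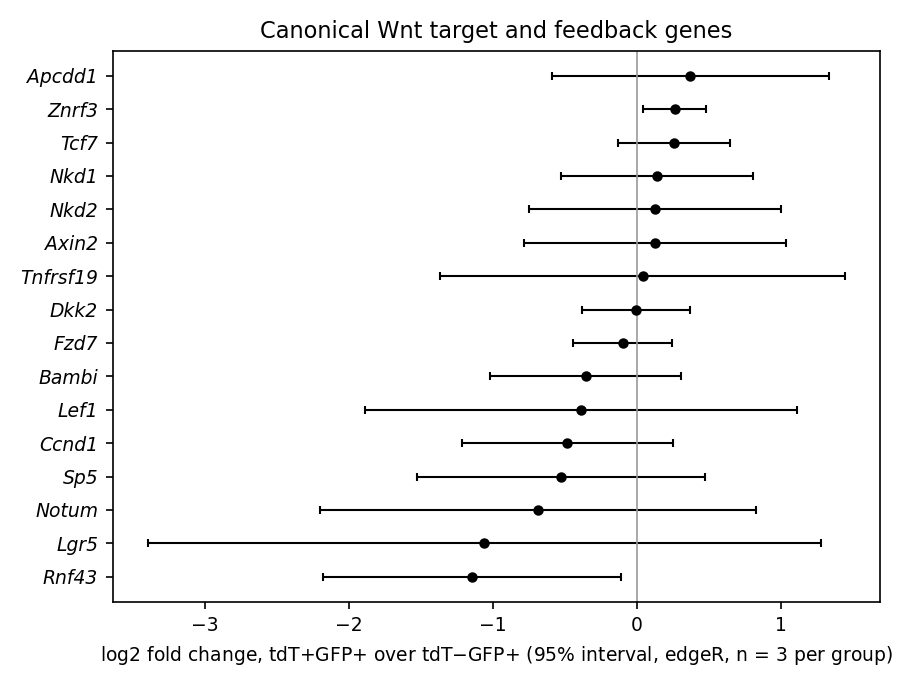
Log2 fold change of tdT+GFP+ over tdT-GFP+ cells (points) with 95% intervals (lines) for the 16 tested canonical Wnt target and feedback genes, n = 3 libraries per group. The points lie on both sides of 0, from -1.15 for Rnf43 to 0.37 for Apcdd1, and the interval of Axin2 runs from -0.79 to 1.03.

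The contractile and fibrillar matrix programmes of myofibroblasts were high in both populations and did not pass the test over all libraries, whereas lists of matrix crosslinking and TGF-beta genes were called higher in tdT+GFP+ cells at the preset correlation only, with small medians. The collagen genes Col1a1 and Col3a1, named for their abundance after their values were seen, had 20580 and 18894 CPM in tdT+GFP+ cells and 18434 and 17264 CPM in tdT-GFP+ cells, with log2 fold changes of 0.16 and 0.13 (adjusted p = 0.722 and 0.794) that turned to -0.02 and -0.05 without both libraries of replicate 3. Without replicate 3 of tdT-GFP+ cells alone they were 0.03 and -0.0013, and without its replicate 1 they were 0.30 and 0.34. Of 25 fibrillar matrix genes 14 had positive values (median 0.07, adjusted p = 0.648). Elastin (Eln) had -0.58 (SE 0.16), Fbln1 -0.50 (SE 0.20) and Col12a1 0.74 (SE 0.36). Of 16 contractile genes 11 had positive values (median 0.21, mean -0.03, test direction up, adjusted p = 0.118). Without replicate 1 of tdT-GFP+ cells the fibrillar matrix and contractile lists were called higher (medians 0.29 and 0.27, adjusted p = 0.00063 and 0.00047), as was the contractile list without replicate 2 of tdT+GFP+ cells (adjusted p = 0.0436). Both were called higher without both libraries of replicate 1 (medians 0.33 and 0.29, adjusted p = 3.0e-05 and 0.00021). Without both libraries of replicate 2 the fibrillar matrix list was called lower (median -0.01, adjusted p = 0.0069). The smooth muscle myosin gene Myh11 had -1.13 (SE 0.39) at 136 ± 18.1 against 298 ± 159 CPM, while Tpm2 had 0.38 (SE 0.14) and Tagln had 0.54 (SE 0.24). Without replicate 3 of tdT-GFP+ cells Myh11 had -0.67 and Col12a1 0.48, and without its replicate 1 Col12a1 had 1.14 and Tagln 0.87. The lowest values over the alternatives were 0.33 for Col12a1 and 0.32 for Tagln. Of 21 matrix crosslinking and remodelling genes 16 had positive values, and the list was called higher (median 0.12, adjusted p = 0.0143 with a preset correlation, adjusted p = 0.681 with an estimated correlation). Its members Loxl4, Lox and Plod2, which encode collagen crosslinking enzymes, had 0.56 (SE 0.17), 0.53 (SE 0.23) and 0.39 (SE 0.15). Lox had 0.84 and Plod2 0.59 without replicate 1 of tdT-GFP+ cells. Over the alternatives Loxl4 ran from 0.39 to 0.71, Lox from 0.36 to 0.84 and Plod2 from 0.28 to 0.59. The 21 TGF-beta pathway genes were also called higher (median 0.16, 12 positive, adjusted p = 0.0183 preset, adjusted p = 0.601 with an estimated correlation). Inhba, an activin subunit gene, had 0.62 (SE 0.23) and Ccn1 had 0.60 (SE 0.21), while Id1, a target of bone morphogenetic protein signalling, had -0.69 (SE 0.24). In both lists 0 members passed over the list alone in edgeR. DESeq2 called Inhba and Ccn1 higher with the kidney as a block (adjusted p = 0.0308 and 0.0380) and not without it (0.202 and 0.128), and it called Eln lower (0.0460, and 0.0174 with the block). The matrix remodelling call was lost without replicate 3 of tdT+GFP+ cells (adjusted p = 0.0898) or replicate 2 or 3 of tdT-GFP+ cells (0.0530 and 0.196). The TGF-beta call was lost without replicate 2 of tdT+GFP+ cells (0.0881) or replicate 2 or 3 of tdT-GFP+ cells (0.128 and 0.0658), and in limma-voom (0.0697). With quality weights in limma-voom both calls were lost (0.0602 and 0.0668), as they were without both libraries of replicate 2 (0.0660 and 0.507) or 3 (0.558 and 0.0525).

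Endothelial genes were lower in tdT+GFP+ cells, by more than 2-fold in the median over all 6 libraries. All 18 tested endothelial markers had negative log2 fold changes (median -1.28, quartiles -1.46 and -1.15), and the list was called lower (adjusted p = 6.1e-23 with a preset correlation, adjusted p = 0.287 with an estimated correlation). When adjusted over the list alone 13 members passed, and 0 over all genes. The median was -0.98 without replicate 3 of tdT-GFP+ cells and -0.94 without both libraries of replicate 3, less than 2-fold. With the kidney as a block 6 passed over the list alone. The angiopoietin receptor family gene Tie1 had 48.5 ± 11.6 against 143 ± 37.0 CPM (log2 fold change -1.57, SE 0.25), and the junction gene Esam had 34.6 ± 9.77 against 87.9 ± 17.7 CPM (-1.35, SE 0.24). The endothelial transcription factor gene Erg had -1.26 (SE 0.23) and the phosphatase gene Ptprb had -1.15 (SE 0.22). The differences of the list mean in kidneys 1, 2 and 3 were -1.45, -0.52 and -1.58 on the log2 scale. DESeq2 called 10 of the 18 lower, where 0.326 would be expected among its 264 lower calls (Fisher's exact test, adjusted p = 1.9e-12), and 8 with the kidney as a block. Fisher's test takes the members as independent, but they varied together across libraries (estimated correlation 0.503). The number passing over the list alone was 6 without replicate 1 or 3 of tdT+GFP+ cells and 6 without replicate 1 or 3 of tdT-GFP+ cells, and it was 4 without both libraries of replicate 1 and 6 without both of replicate 3. The share of counts on gene models that overlap ribosomal RNA sequence differed in the same way between libraries, 0.549% ± 0.117 in tdT+GFP+ and 1.08% ± 0.223 in tdT-GFP+ libraries (SD, n = 3, exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows).

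**Figure D3:**
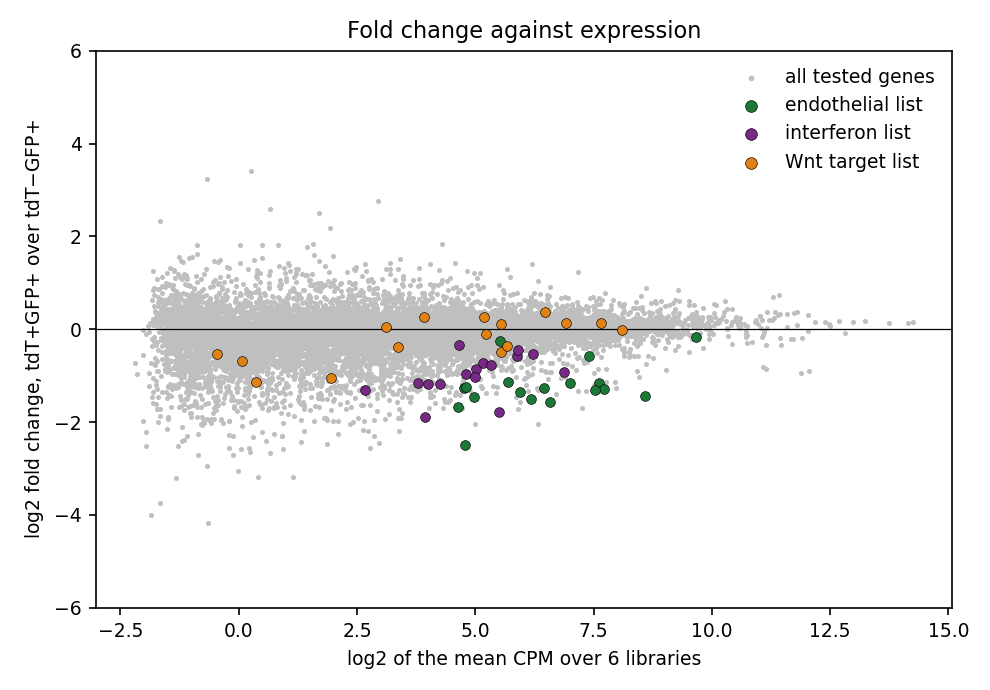
Log2 fold change of tdT+GFP+ over tdT-GFP+ cells against the log2 of the mean CPM over the 6 libraries for all 15462 tested genes (grey), with the 18 endothelial (green), 16 interferon (purple) and 16 Wnt target genes (orange) marked. The endothelial and interferon genes all lie below 0, with medians of -1.28 and -0.94, and the Wnt targets lie on both sides with a median of -0.05.

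Lists of Hedgehog and Notch genes and of markers of mural cells, the pericytes and smooth muscle cells around vessels, were lower along with the endothelial genes. Of 17 Hedgehog and Notch genes, 14 had negative values (median -0.30), and the list was called lower (adjusted p = 1.3e-07 preset, adjusted p = 0.287 with an estimated correlation). The 7 members that passed over the list alone included the Notch ligand gene Dll4 (33.5 ± 3.47 against 71.3 ± 18.2 CPM, log2 fold change -1.09, SE 0.20), the receptor genes Notch4 (-1.07, SE 0.20) and Notch1 (-0.41, SE 0.08) and the Notch target Nrarp (-1.33, SE 0.26). Dll4 and Notch4 are known mainly from endothelium. The members named here are all Notch genes, and the list was not split by pathway. The call of this joint list therefore cannot be assigned to Hedgehog genes, whose part was not tested. Of these 7, 4 passed without replicate 3 of tdT-GFP+ cells. Of 18 pericyte, vascular smooth muscle and mesangial markers, 15 had negative values (median -0.53, adjusted p = 1.6e-06 preset, adjusted p = 0.336 with an estimated correlation). Over the list alone 5 passed. With the kidney as a block 2 passed, and 0 without replicate 1 of tdT+GFP+ cells, without replicate 1 or 3 of tdT-GFP+ cells or with a filter of 1 CPM in 3 libraries. The number was 3 without replicate 3 of tdT+GFP+ cells and 8 without replicate 2 of tdT-GFP+ cells. The pericyte gene Rgs5 had 149 ± 48.5 against 357 ± 115 CPM (-1.26, SE 0.32), Rergl had -2.19 (SE 0.58) and Notch3 had -0.49 (SE 0.13). Resident fibroblast markers were called lower (13 of 18 negative, median -0.38, adjusted p = 0.0285 preset, adjusted p = 0.481 with an estimated correlation). Their leading members Ly6a (-1.06, SE 0.29) and Cd34 (-1.39, SE 0.46) are also known from endothelium. Over the list alone 0 members passed, and 1 with the kidney as a block. DESeq2 called each of the genes named in this paragraph lower, and with the kidney as a block it did not call Notch1, Rergl, Notch3 and Cd34. The resident fibroblast call was lost without replicate 1 or 3 of tdT+GFP+ cells (adjusted p = 0.0858 and 0.0868), without replicate 1 or 2 of tdT-GFP+ cells (0.0587 and 0.0670) and without both libraries of replicate 1 (0.116).

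Interferon response genes were lower in tdT+GFP+ cells in every kidney. All 16 tested genes had negative log2 fold changes (median -0.94, quartiles -1.18 and -0.68), and 15 passed when adjusted over the list alone, 0 over all genes. The number over the list alone was 7 without both libraries of replicate 2. The list was called lower (adjusted p = 3.8e-25 with a preset correlation, adjusted p = 0.287 with an estimated correlation), and the list mean differed by -0.92, -1.06 and -0.92 in kidneys 1, 2 and 3. The antiviral gene Rsad2 had 20.3 ± 5.83 against 69.9 ± 25.3 CPM (log2 fold change -1.78, SE 0.32), Ifi44 had 6.53 ± 1.74 against 24.3 ± 9.64 CPM (-1.90, SE 0.34), Cmpk2 had -1.19 (SE 0.21) and Usp18 had -1.30 (SE 0.19). DESeq2 called 10 of the 16 lower, where 0.290 would be expected (Fisher's exact test, adjusted p = 7.1e-13), and 12 with the kidney as a block. These members also varied together across libraries (estimated correlation 0.677), while Fisher's test takes them as independent. The ribosomal RNA share and the endothelial genes moved between the groups in the same way as these genes. Inflammatory chemokine and cytokine genes were called higher (16 of 22 positive, median 0.57, adjusted p = 0.0183 preset, adjusted p = 0.601 with an estimated correlation), with 0 members past the threshold over the list alone in edgeR and 1 with the kidney as a block. Their list means were 4.73, 4.83 and 4.13 in tdT+GFP+ and 4.32, 3.98 and 4.49 in tdT-GFP+ libraries 1, 2 and 3. Macrophage marker means ordered the libraries alike, at 5.46, 5.87 and 4.26 against 4.62, 4.16 and 5.45, and the share of macrophage RNA in the chemokine values was not tested. Il6 had 124 ± 39.2 against 66.3 ± 18.9 CPM (0.90, SE 0.31) and the monocyte chemokine gene Ccl7 had 1.31 (SE 0.43). The interferon-induced chemokine genes Cxcl9 (-1.22, SE 0.31) and Cxcl10 (-1.23, SE 0.39) had negative values. With the kidney as a block DESeq2 called Il6 higher (adjusted p = 3.3e-06, and 0.0984 without the block) and Cxcl10 lower (0.0110, and 0.0513 without), while it called Cxcl9 lower only without the block (0.0413, and 0.125 with it). The chemokine call was lost without replicate 2 of tdT+GFP+ cells (adjusted p = 0.106), without replicate 1 or 2 of tdT-GFP+ cells (0.0558 and 0.206), without both libraries of replicate 1 or 2 (0.0748 and 0.585), and in limma-voom (0.0759, and 0.0777 with quality weights).

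**Figure D4:**
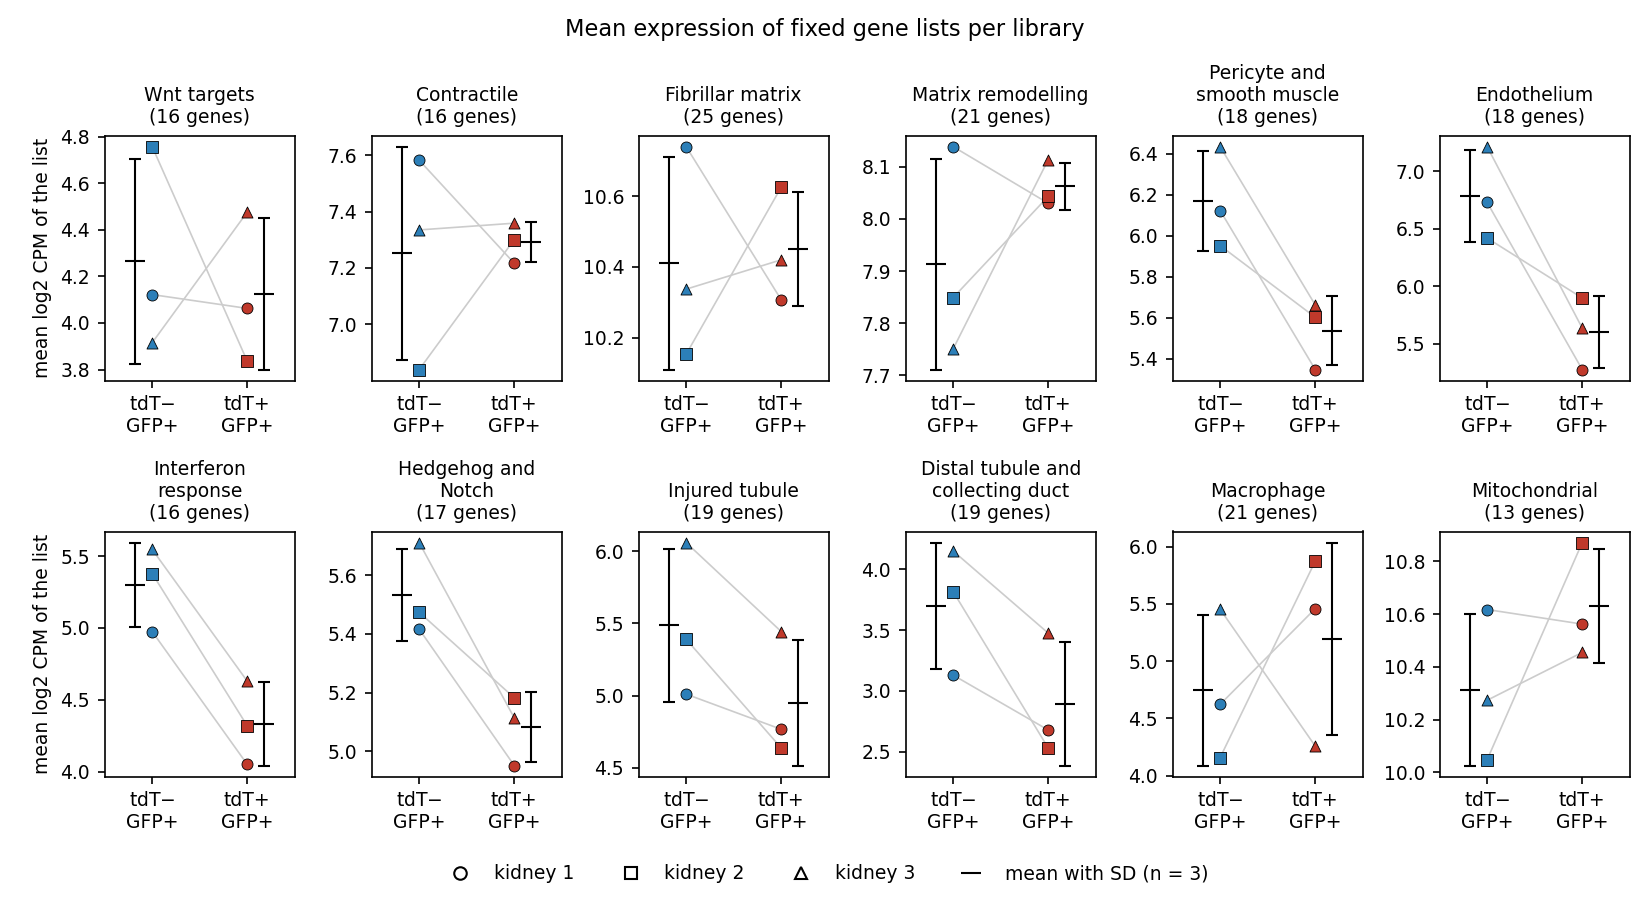
Mean log2 CPM of 12 gene lists in each library of tdT-GFP+ (blue) and tdT+GFP+ cells (red), with symbols for kidneys 1 to 3, lines joining libraries of 1 kidney, and the mean and SD of each group (n = 3). The endothelial, interferon, Hedgehog and Notch, and pericyte means do not overlap between the groups and are lower in tdT+GFP+ cells, while Wnt target, contractile and fibrillar matrix means overlap.

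Kidney epithelial transcripts were present in both sorts and lower on average in tdT+GFP+ cells for the distal and injured tubule lists. The library means of both lists overlapped between the groups (exact permutation p = 0.2 and 0.3). The share on models overlapping ribosomal RNA moved the same way, at 0.577%, 0.420% and 0.648% in tdT+GFP+ and 0.838%, 1.11% and 1.28% in tdT-GFP+ libraries 1, 2 and 3. Whether RNA quality bears on these lists was not tested. Of 19 loop of Henle, distal tubule and collecting duct markers, 18 had negative values (median -0.64, adjusted p = 1.2e-06 preset, adjusted p = 0.601 with an estimated correlation). Over the list alone 0 passed, and 6 with the kidney as a block. The sodium chloride cotransporter gene Slc12a3 had 13.5 ± 1.24 against 35.1 ± 22.4 CPM (log2 fold change -1.38, SE 0.42), the calbindin gene Calb1 had -1.27 (SE 0.40) and Egf had -1.72 (SE 0.55). All 19 injured tubule and repair markers had negative values (median -0.52, adjusted p = 0.00088 preset, adjusted p = 0.681 with an estimated correlation), with 0 past the threshold over the list alone and 1 with the kidney as a block. The keratin gene Krt8 had -0.91 (SE 0.41), clusterin (Clu) -1.03 (SE 0.49) and the nephric transcription factor gene Pax8 -0.76 (SE 0.36). The injured tubule call was lost without replicate 3 of tdT-GFP+ cells (adjusted p = 0.145). Of 22 proximal tubule markers 14 had negative values (median -0.12, adjusted p = 0.642), Kap, a kidney androgen-regulated gene, having -2.04 (SE 0.63). Without replicate 2 of tdT+GFP+ cells this list was called lower (median -0.60, adjusted p = 0.0030), as it was without both libraries of replicate 2 (median -0.85, adjusted p = 0.00037), and without both libraries of replicate 3 it was called higher (median 0.73, adjusted p = 6.3e-07). Of 10 podocyte and parietal markers 7 had negative values (median -0.31, adjusted p = 0.128, and 0.0499 with no count filter), and the library means of this list did not overlap between the groups. The member that passed over the list alone was Podxl, a sialomucin gene also used by endothelium, at 82.3 ± 12.9 against 205 ± 68.2 CPM (-1.32, SE 0.25), and it did not pass without replicate 1 or 2 of tdT+GFP+ cells. DESeq2 called Slc12a3 and Podxl lower with and without the block, and called Calb1, Egf, Krt8, Clu and Kap lower only with it (adjusted p from 8.3e-06 to 0.00038). These sizes rested in part on single libraries. Over the alternatives the list medians ran from -1.11 to -0.48 for distal tubule and from -0.97 to -0.26 for injured tubule genes. Without replicate 3 of tdT-GFP+ cells the log2 fold changes were -0.72 for Slc12a3, -1.14 for Kap, -0.57 for Krt8, -0.59 for Clu and -0.30 for Pax8. Without replicate 3 of tdT+GFP+ cells they were -2.59 for Egf, -1.40 for Krt8 and -1.59 for Clu.

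Macrophage and mitochondrially encoded transcripts were called higher in tdT+GFP+ cells at the preset correlation only. Of 21 macrophage markers 17 had positive and 4 had negative values (median 0.66, adjusted p = 0.0109 preset, adjusted p = 0.840 with an estimated correlation), and 0 passed over the list alone. Among the positive ones, the mannose receptor gene Mrc1 had 106 ± 60.4 against 39.9 ± 15.7 CPM (log2 fold change 1.41, SE 0.55) and Itgam had 1.29 (SE 0.66, and 0.82 without replicate 2 of tdT+GFP+ cells), each higher in 2 of 3 kidneys. The macrophage call was lost without replicate 2 of tdT+GFP+ cells (adjusted p = 0.501), without replicate 1 or 2 of tdT-GFP+ cells (0.272 and 0.261) and without both libraries of replicate 1 or 2 (0.441 and 0.606). All 13 mitochondrially encoded genes had positive values (median 0.29, adjusted p = 7.4e-05 preset, adjusted p = 0.601 with an estimated correlation), and 0 passed over the list alone. That call was lost without both libraries of replicate 2 (adjusted p = 0.379). The mitochondrial share of counts was 3.07% ± 0.294 against 2.69% ± 0.246 (SD, n = 3, exact permutation p = 0.2). Cell cycle genes were not called (20 of 24 positive, median 0.06, adjusted p = 0.0570), though they were with no count filter (0.0344), in limma-voom (0.0451, and 0.0353 with quality weights) and without replicate 2 of tdT+GFP+ cells (0.0436), with Rrm2, a nucleotide reductase gene, at 0.41 (SE 0.13). The library means of the cell cycle list did not overlap between the groups. Medians of the other lists not called were -0.05 for 24 stromal transcription factors, in which Tbx18 had 1.18 (SE 0.42), and -0.09 for 21 immediate early and dissociation stress genes, in which Atf3 had -0.60 (SE 0.23). The stress genes were called lower without replicate 3 of tdT+GFP+ cells or replicate 3 of tdT-GFP+ cells (adjusted p = 4.0e-06 and 0.0298) and higher without replicate 2 of tdT-GFP+ cells (0.0274). Without both libraries of replicate 3 they were called lower (median -0.26, adjusted p = 6.0e-10) and without both of replicate 2 higher (median 0.24, adjusted p = 4.1e-05). Medians were 0.02 for 16 basement membrane genes, -0.04 for 23 growth factors and receptors, 0.13 for 12 neutrophil and lymphocyte markers (called higher without both libraries of replicate 3, adjusted p = 0.0073), -0.06 for 7 Schwann cell and neuronal markers (mean -0.56, with library means that did not overlap between the groups), -0.04 for 20 hypoxia and glycolysis genes, 0.00 for 21 nuclear oxidative phosphorylation genes and 0.02 for 13 senescence genes. The basement membrane list had a mean of -0.10 and a test direction of down, and the senescence list had a mean of 0.01 and a test direction of down. The 4 tested red blood cell genes, too few for the list test, had a median of -1.39. Their mean log2 CPM was -2.56, -1.16 and 1.96 in tdT+GFP+ and 2.07, 1.70 and 1.84 in tdT-GFP+ libraries 1, 2 and 3. Library 3 of tdT+GFP+ cells thus lay at the tdT-GFP+ level.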

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

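In edgeR and limma-voom the numbers of genes higher and lower were 0 under every alternative, including the paired fit with kidney as a replicate block and each left-out library. The DESeq2 Wald test gave 17 higher and 264 lower, and with the replicate block 41 higher and 237 lower. Zfp366 had -1.43 (SE 0.18, unadjusted p = 0.00014) in edgeR and -1.43 (SE 0.21, 2.3e-11) in DESeq2. Tie1 had -1.57 (SE 0.25, 0.00051) and -1.57 (SE 0.25, 4.5e-10). For these genes the tests differ in the reference distribution, a normal one in DESeq2 and an F distribution with few degrees of freedom (median 6.67) in edgeR. The cause over all genes was not tested. Of the 89 tested genes named in the text, compared under 20 alternatives (19 for Msln, Wnt16 and Hbb-bs, which 1 alternative leaves out), 82 never changed sign. Without replicate 3, Pi16, Clec3b and Itgbl1 turned from negative to 0.41, 0.50 and 0.63, and without replicate 2 they had -3.83, -3.76 and -3.96. Clec3b and Itgbl1 also turned to 0.16 and 0.14 without replicate 1, and Itgbl1 to 0.055 and 0.078 without replicate 3 of tdT+GFP+ or of tdT-GFP+ cells. Without replicate 3, Apcdd1 turned to -0.12 (up to 1.05 over left-out libraries), Col1a1 to -0.017 and Col3a1 to -0.050, with the latter 2 reaching 0.30 and 0.37, and Col3a1 also turned to -0.0013 without replicate 3 of tdT-GFP+ cells. Axin2 turned to -0.12 without tdT+GFP+ replicate 3, -0.13 without tdT-GFP+ replicate 3 and -0.38 without replicate 3, with a range of -0.38 to 0.72 over left-out libraries. Acta2 ranged from 0.24 to 0.76. Of 12 lists called with the preset correlation, 5 (endothelium, interferon, Hedgehog and Notch, pericyte and distal tubule) kept their call in every alternative with a list test except the estimated correlation, which called 0 higher and 0 lower, with and without the replicate block. Quality weights in limma-voom gave 3 lists higher, and left-out libraries gave 2 to 6 higher and 6 to 9 lower; the cause of these changes was not tested. The macrophage list turned to a median of -0.0018 without replicate 2 and reached 1.46 without replicate 3. The kidney block changed no list call at the preset correlation and no single gene call in edgeR. Beside the counts over a list alone given in the report, the block gave 1 gene each for Wnt receptors, resident fibroblast, chemokine and hypoxia genes, from 0. From 0 over the list alone, leaving out replicate 3 of tdT+GFP+ cells gave 10 chemokine genes higher and 3 lower, 8 distal and 7 injured tubule genes and 1 Wnt receptor gene lower and 2 macrophage genes higher. Leaving out replicate 1 of tdT-GFP+ cells gave 6 TGF-beta genes higher and 1 lower, 5 matrix remodelling, 3 Wnt ligand, 3 mitochondrial and 1 chemokine gene higher, and 5 distal tubule and 1 resident fibroblast gene lower. Without replicate 2 of tdT-GFP+ cells 1 Wnt ligand and 2 resident fibroblast genes were lower and 1 resident fibroblast gene higher, and without its replicate 3 there was 1 distal tubule gene lower. Leaving out the ribosomal RNA overlapping models, an alternative added after seeing the data, left 5 higher and 7 lower. Depth limits genes near the floor of 3 counts, 0.0908 to 0.117 CPM, and its part in the spread of other genes at low counts was not tested. In simulation, with genes drawn independently, 47.3% of 2-fold changes were called.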

Other observations

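The tests of the endothelial mean as a covariate and of the Axin2 interval were chosen after the results were seen. Some variation between libraries crossed the sorted groups. Pi16, a marker of adventitial fibroblasts, chosen like the other genes of this paragraph after its values were seen, stood at 4.45, 58.8 and 3.42 CPM in tdT+GFP+ libraries 1, 2 and 3 and at 42.2, 5.27 and 69.8 CPM in tdT-GFP+ libraries 1, 2 and 3. Clec3b had 0.915, 13.5 and 0.723 against 9.65, 0.448 and 12.5 CPM, and Itgbl1 had 1.01, 12.3 and 0.152 against 7.77, 0.710 and 10.8 CPM. Axin2 had 52.8, 29.7 and 64.2 against 43.0, 64.2 and 27.3 CPM in the same order. Lyve1, a gene of lymphatic endothelium and some macrophages, had 10.3, 7.64 and 0.837 against 1.12, 1.53 and 1.52 CPM. The beta-globin gene Hbb-bs had 0.244, 0.580 and 7.65 against 7.74, 4.78 and 7.34 CPM. PC1 and PC2 held 39.2% and 34.7% of the variance.

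The lower level of endothelial genes in tdT+GFP+ cells is consistent with a smaller share of endothelial RNA in that sort. Another list of 20 endothelial genes, written before its values were seen, was negative in 20 of 20 with a median of -1.13. It was measured in the same libraries, where endothelial genes varied together. Any cause that moves endothelial genes together would give this result, so it is not separate support for a smaller share. The 3 most abundant genes of the main list differed in size: Plvap had 207 against 564 CPM and Cdh5 123 against 301 CPM, but Eng, which stromal cells also use, had 766 against 856 CPM. A gate on GFP would remove endothelial cells without the reporter, and whether the tdT-GFP+ sort held such cells, doublets or free RNA, or mural cells with different expression, was not tested.

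Interferon genes were lower by a median of -0.94. A smaller share of endothelial RNA could contribute, but with the endothelial list mean as a covariate the interferon median was -0.54. The covariate differs between the groups with 3 libraries each, so it and the sort cannot be told apart. In kidneys 1, 2 and 3 the endothelial list mean differed by -1.45, -0.52 and -1.58, and the interferon list mean by -0.92, -1.06 and -0.92. By these kidney numbers, the interferon difference was largest where the endothelial one was smallest. A difference in interferon response between Axin2-labelled and unlabelled cells stays open as untested.

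Axin2 mRNA did not separate the sorts. The spread between libraries may hide a difference, since the 95% interval reached 1.03, about a doubling. The label was laid down by tamoxifen on days 2 and 4 and the RNA taken on day 6, so a loss of Axin2 expression in between stays open as untested.

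The 6 libraries can be split into 3 against 3 in 10 ways, too few for a share under 0.05. With edgeR the real split gave 0 genes and the highest other split 7. Any split gives at least 0 genes, so that 10 of 10 gave as many decides nothing. With DESeq2 the real split gave 281 genes and the highest other 437, with 4 of 10 giving as many. For gene lists at the preset correlation the real split gave 12 and the others 7 to 15, again with 4 of 10 giving as many. Every split thus called lists at the preset correlation, so such a call alone does not mark the sort. At an unadjusted p under 0.05 the real split gave 1650 genes and the others 27 to 2510, with 2510 and 1666 above the real one. Among the splits that part all 3 pairs, DESeq2 gave 281 genes for the real one and 414, 437 and 3 for the others, and the list test gave 12 lists for the real one and 10, 9 and 12 for the others. The split with 437, which also gave the 7 genes in edgeR, sets tdT+GFP+ replicates 1 and 3 and tdT-GFP+ replicate 2 against the rest, as the values of Pi16 do.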
